A study of Mus musculus with 6 samples.

How the data were processed

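The data are droplet libraries of mouse retina in 6 groups of 1 library each (control, and 2h, 8h, 1d, 3d and 7d after optic nerve crush). Libraries were made with the 10x Genomics 3' v3 chemistry, per the labels' protocols, which speak of single cells where the series title speaks of single nuclei. The matrices hold whole-number UMI counts per gene and barcode made with Cell Ranger 7.0.1, per the file headers. Per the submitters' processing notes the tools were Cell Ranger and STAR and the genome build mm10; whether intronic reads were counted, and how barcodes were filtered, is not given in the sources used here. In the deposited matrices the counts cover 32285 genes, and no barcode has fewer than 500 UMIs, so shallower droplets, and with them the free RNA of empty droplets, could not be measured. Gene positions come from GENCODE M21 (Ensembl 96, GRCm38, the assembly also called mm10), matched on Ensembl gene ID for 644 of 645 genes looked up. Of 518 gene symbols in the fixed lists 514 were in the matrices; Clec7a, Ctgf, Cyr61 and Ero1a were not under those symbols.

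The groups, the gene lists, the cell type markers, the rule for naming genes and most alternatives were set before the data were examined. The exceptions are the numerical rule by which clusters were named, the choice of which lists to print, the 1.5-fold limit used to count list medians, and the alternatives named as later additions. Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept. Doublet scores were computed with scanpy's Scrublet (simulated doublet ratio 2), whose automatic threshold called 920, 10, 9, 1402, 1 and 2 barcodes and so did not work in 4 of the libraries. In place of it the highest-scoring barcodes of each library were removed at 0.8% per 1000 barcodes, which took out 2757, 1860, 2728, 818, 1225 and 1498. The rate rises with the number of barcodes, so the share removed was 14.9% in control and 8.10% at 1d.

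The remaining 77523 nuclei were scaled to a common total, log-transformed, reduced to 2000 variable genes and 40 principal components, joined by 15 nearest neighbours and clustered together by the Leiden method at resolution 1, with no batch correction. Of 76 clusters 61 were named and 15 left unnamed. A cluster took a class name where at least 3 markers of that class were raised 1.5-fold or more and its 10 leading genes held no more markers of another class than of its own; clusters with fewer markers, with mixed markers, or with shallow nuclei and no leading marker stayed unnamed. That rule was written after the clusters were seen and holds 1 exception made for cluster 4, which has an endothelial marker and no Müller glia marker among its leading genes; it was kept and is compared by number for that reason. RGC-like nuclei fell into 9 clusters. The cells of a library are not replicates, so UMI counts were summed over the nuclei of a class in a library, and CPM of that sum were compared with control as a log2 ratio, with 0.5 counts added. The interval of a ratio is the exact conditional binomial interval for 2 counts at 95%. Shares have exact Clopper-Pearson intervals. A gene with 0 counts in control is given as at least N-fold higher, N being its level over that of 3 counts in control; this leaves out the counting error of the ONC count, so the lower limit of the binomial interval lies below N. Intervals and limits treat each UMI of a sum as independent, so they cover counting error only and leave out spread between nuclei. They also leave out differences between mice, dissections or library preparations, which 1 library per group cannot show. A class was compared where it had at least 50 nuclei in both libraries.

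A list median is taken over members with at least 10 UMIs in the 2 libraries. Its interval comes from 1000 Poisson redraws of the counts, and its percentile from 10000 random lists of equal size drawn within 20 bins of mean expression. With members at 0 counts set to their limit, each list median printed was the same. Medians were computed for lists with at least 3 measured members, which were all 34 in the classes other than horizontal-like nuclei (30 to 32 lists) and astrocyte-like nuclei, and printed for those that answer the design's questions. For RGC-like nuclei and clusters 4 and 51 the rule for single genes took, per ONC library, the 4 higher and 2 lower genes with the interval bound farthest from 0, among genes with at least 20 UMIs and a class level of at least 0.5 times that of other nuclei; for each other class it took 6 higher and 3 lower over all 5 ONC libraries. Mitochondrial, ribosomal and haemoglobin genes, Malat1, sex-linked genes, unnamed gene models and markers of other classes were not eligible. Up to 4 members of each list with the best bounds, and members needed to describe a list, were named as well; Pou4f1, Slc17a6, Gap43, Mt1 and Gfap were among these, some chosen after their values were seen. A ligand or receptor counts as detected at 10 CPM and 10 UMIs. On sex-linked genes 0 libraries stood apart from the rest, but the mix of sexes within a library was not estimated.

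The ratio step was tested on simulated counts with 200 changed genes. All simulated counts were Poisson draws from the control profile, the case the interval is built for, so coverage near 95% was given in advance. Spread between nuclei and between preparations was not simulated, so the shares below are for counting error alone. For RGC-like nuclei at 7d (16307 genes), the smallest ONC sum of that class, the interval left out 0 for 41.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold, and it covered the true ratio for 96.2% of genes. For RGC-like nuclei at 3d (16849 genes) the shares were 59.7%, 80.6% and 95.5%. For clusters 4 and 51 at 3d (14714 genes) they were 65.7%, 71.6% and 95.5%. A simulated 2-fold change of every axon injury gene came back as a median of 0.86 at 3d and 0.94 at 7d.

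The alternatives were a stricter filter (500 genes, 5% mitochondrial), no doublet removal, Leiden resolution 2, naming each nucleus by its highest marker score, other denominators for shares, edgeR's TMM factors on the class sums with no test, subtraction of estimated free RNA, thinning of each nucleus to 1000 UMIs, list minima of 1 and 50 UMIs, 2 added counts, and the median of the other 4 ONC libraries as the reference. Free RNA was estimated from rod genes in other classes, with the profile of the whole library standing in for it. The estimate came to 42.0% of the library profile for RGC-like nuclei in control and 31.3% at 1d. It was 85.1% and 59.8% for clusters 4 and 51, 82.4% in control for bipolar-like nuclei, and 99.8% in control and 104.6% at 8h for cone-like nuclei. It thus removes a large part of each sum, leaves little in cones, and rests on that stand-in. The share differed between control and the ONC libraries, and how far that alone moves a ratio was not tested. The TMM factors moved the median of all genes by over 0.1 in RGC-like nuclei at 3d (-0.12), in clusters 4 and 51 at 2h, 1d and 7d (0.12, 0.12 and 0.11) and in horizontal-like nuclei at 2h and 1d (0.15 and 0.12). Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Ligand and receptor pairs were not scored, since that needs a database not used here, and RNA velocity and reads were not analysed here.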

Results

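Retinal nuclei of adult C57BL/6J mice were profiled by droplet RNA sequencing in 6 libraries, 1 per group: a control and retinas taken 2h, 8h, 1d, 3d and 7d after optic nerve crush (ONC), a mechanical injury to the axons of retinal ganglion cells (RGCs). The series addresses how neurons, glia and vessels of the retina respond in the first hours to days after this injury. In the order control, 2h, 8h, 1d, 3d and 7d, the libraries held 18573, 15252, 18469, 10118, 12387 and 13685 barcodes and 54.5, 62.0, 56.0, 46.8, 51.2 and 56.5 M unique molecular identifiers (UMIs). After filtering and doublet removal 15797, 13385, 15734, 9286, 11138 and 12183 nuclei remained, with medians of 1695, 2445, 1924, 2647.5, 2442 and 2352 UMIs. How many mice each library came from, and whether the control retinas came from uninjured mice or from the uncrushed eye, is not given in the sources used here. With 1 library per group there was no test, and no difference reported here has a replicate check. All intervals are 95% intervals that cover counting error only, and all 5 ONC libraries were compared with the same control library.

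RGC-like nuclei, the neurons whose axons form the optic nerve, made up 5.55% of control nuclei (877 of 15797; exact binomial interval 5.20 to 5.92). Their share was 5.32% at 2h, 5.18% at 8h, 5.26% at 1d and 4.84% at 3d, and 1.78% at 7d (217 of 12183; 1.55 to 2.03). The 7d share was 0.321 times that of control (0.275 to 0.373). Per 100 amacrine-like nuclei, interneurons without an axon in the optic nerve, there were 40.8 RGC-like nuclei in control and 31.8, 33.2, 32.7, 34.0 and 12.5 in the 5 ONC libraries. Cluster 15 held the most RGC-like nuclei in control and at 2h, 8h and 1d (24.6% to 31.4%), while cluster 25 held 435 of 539 at 3d and 115 of 217 at 7d. When each nucleus instead took the class with its highest marker score, the 3d ratio was 0.440 rather than 0.872 and the 7d ratio 0.195 rather than 0.321, so both depend on how nuclei are named. The RGC markers in that score are also in the RGC identity list, which was lower at 3d and 7d. The score can thus leave out RGC nuclei in which these markers fell, which also bears on gene levels under it.

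Among other classes, clusters 4 and 51, the clusters richest in Müller glia markers, made up 5.50% of nuclei in control and 8.17%, 4.18%, 8.39%, 7.71% and 8.78% at 2h, 8h, 1d, 3d and 7d. Microglia-like nuclei, the resident immune cells of the retina, numbered 35 in control and 51 at 7d, a share 1.89 times that of control (1.21 to 2.99). At 2h, 8h, 1d and 3d the interval of the microglia ratio included 1. Endothelial-like nuclei numbered 274 in control and 34, 20, 28, 28 and 44 in the ONC libraries, with ratios of 0.146, 0.0733, 0.174, 0.145 and 0.208. Pericyte-like nuclei numbered 40 in control and 11, 6, 1, 1 and 12. Nuclei like the retinal pigment epithelium, the layer behind the retina, numbered 7 in control and 49, 10, 33, 26 and 8, with ratios of 8.26 at 2h (3.72 to 21.6), 8.02 at 1d and 5.27 at 3d. By highest marker score these ratios were 1.44, 1.17 and 1.28, so they depend on how nuclei are named, and a different dissection was not tested. Clusters left unnamed held 25.4% of control nuclei and 8.02%, 18.6%, 9.05%, 33.7% and 16.02% of the ONC libraries, and unnamed cluster 3 alone held 18.2% of control and cluster 5 held 23.6% at 3d. Shares of rods and of other classes rest on where these nuclei belong, and at clustering resolution 2 the ratio of the rod share at 3d was 1.38 rather than 0.611.

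**Figure D1:**
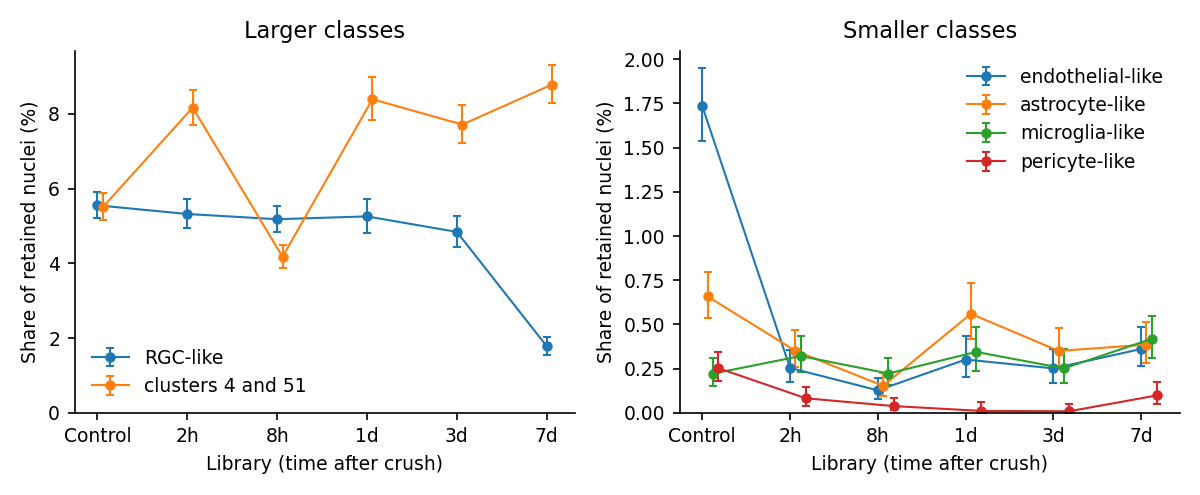
Share of retained nuclei (%) per library for RGC-like nuclei and clusters 4 and 51 (left) and for 4 smaller classes (right); points are single libraries and bars are exact binomial 95% intervals. The RGC-like share is 1.78% at 7d against 5.55% in control, and the endothelial-like share is highest in control.

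In RGC-like nuclei the first question was which injury genes were higher after the crush, and when. The list of axon injury and regeneration genes had a median log2 ratio to control of -0.57 at 2h (interval -0.82 to -0.21), 0.80 at 8h (0.58 to 1.25), 1.29 at 1d (0.98 to 1.502), 2.75 at 3d (2.58 to 3.11) and 2.33 at 7d (1.97 to 2.70). At least 2-fold higher were 0 of 13 measured members at 2h, 6 of 14 at 8h, 8 of 15 at 1d, 15 of 16 at 3d and 13 of 15 at 7d. Atf3, a transcription factor induced by axon injury (ENSMUSG00000026628, mm10 chromosome 1, 191170296 to 191218039), was at -1.61 at 2h, 2.50 at 8h, 2.14 at 1d, 5.32 at 3d (4.73 to 6.06) and 5.02 at 7d. Sox11, a growth-associated transcription factor (ENSMUSG00000063632, chromosome 12, 27334264 to 27342574), was at 0.35, 2.03, 3.17, 4.44 and 3.80. Stmn4, a regulator of microtubules, was at 2.44 by 8h (2.11 to 2.79) and 3.08 at 1d, whereas the growth cone protein gene Gap43 was at 0.17 at 8h and 2.03 at 3d. Ecel1, an endopeptidase of injured neurons (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521), went from 1 UMI in control to 766 at 3d, a log2 ratio of 9.52 (7.62 to 15.41). In all nuclei outside the class at 3d Ecel1 was at 6.19 and Sprr1a, a cornified envelope gene known from regenerating axons, at 8.47 against 6.95 inside it. The median of the same list over nuclei outside the class was -0.41, 0.24, -0.12, 0.67 and 0.08 from 2h to 7d, so at 2h it was low there too. Genes of other cell types were higher in the RGC-like sums at 3d as well, with reactive gliosis genes at 1.899 (1.17 to 2.05) and crystallins, lens genes, at 1.13 (0.92 to 1.46), against 2.15 and 1.34 outside the class. With each nucleus thinned to 1000 UMIs the list was at 0.027, 1.52 and 2.18 at 2h, 8h and 1d, so the low value at 2h was not seen after thinning. Subtracting estimated free RNA put it at -0.17, 1.74, 2.61, 3.78 and 3.36 from 2h to 7d, and naming by marker score at 1.56 at 7d. With the median of the other 4 ONC libraries as reference, which holds 3d and 7d, the 8h and 1d medians were -0.83 and -0.58.

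Genes of the integrated stress response, which adapts translation and amino acid supply to stress, were at a list median of -0.61 at 2h, 0.58 at 8h, 1.53 at 1d (1.31 to 1.80), 2.18 at 3d (1.96 to 2.45) and 1.403 at 7d (1.21 to 1.68), against -0.51, 0.12, -0.13, 0.29 and -0.07 outside the class. At 3d 14 of 17 measured members were at least 2-fold higher, led by Trib3, a pseudokinase induced by this response, at 3.65 and the serine synthesis enzyme gene Phgdh at 3.59. The list of apoptosis and p53 genes was at 1.11 at 3d (0.93 to 1.43), with 8 of 13 members at least 2-fold higher, and at 0.17 outside the class. Hrk and Bcl2l11, which encode cell death activators, were at 3.31 and 3.22 at 1d, 4.97 and 3.61 at 3d, and 4.86 and 3.68 at 7d, while outside the class Bcl2l11 was at 0.21, 0.48 and 0.24. The STAT3 and gp130 signalling list, a cytokine pathway, was at -0.07 at 2h, 0.64 at 8h, 0.42 at 1d, 1.91 at 3d and 1.48 at 7d, against 0.58 at 8h and 1.02 at 3d outside the class. The kinase gene Pim1, a target of that pathway, was at 3.77 at 3d (3.36 to 4.24) and 0.66 outside the class.

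At 7d the interferon response list, the antiviral programme, had a median of 2.50 in RGC-like nuclei (1.90 to 2.76), with 16 of 19 measured members at least 2-fold higher, against 0.81 outside the class. Its medians at 2h, 8h, 1d and 3d were -0.41, -0.07, 0.21 and 0.86, against -0.22, -0.65, -0.06 and 0.68 outside. Isg15, a ubiquitin-like protein gene of this programme (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), was at -3.22 at 2h and 4.36 at 7d (3.82 to 4.98). The list of MHC class I presentation genes was at -0.86 at 2h and 1.35 at 7d (1.00 to 1.69), with the light chain gene B2m at 1.88, and outside the class at -0.36 and 0.47. At 2h its value within RGC cluster 28 alone was 0.50, of the opposite sign. The immediate early genes, transcription factors of the rapid response to stimuli, were at -1.01 at 2h (-1.38 to -0.85), with 13 of 23 at least 2-fold lower, 0.74 at 8h, 0.04 at 1d, 1.24 at 3d and 0.83 at 7d. Fos was at -2.62 at 2h (-3.56 to -1.86) and at -1.96 outside the class, where the whole list was at -0.91.

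The RGC identity list, made of transcription factors, neurofilaments and other markers of the class, was at 0.09 at 2h, 0.41 at 8h, -0.23 at 1d, -0.87 at 3d (-1.03 to -0.60) and -0.62 at 7d (-0.75 to -0.41). Outside the class it was lower still, at -0.68, -0.19, -1.19, -1.53 and -2.01. At 3d 7 of 14 members were at least 2-fold lower and 3 at least 2-fold higher. The transcription factor gene Pou4f1 (ENSMUSG00000048349, chromosome 14, 104461676 to 104467999) was at -1.03 at 3d and -1.13 at 7d, the RNA-binding protein gene Rbpms at -1.54 and -0.80, and the neurofilament gene Nefh at -2.52 and -0.63. Tubb3, a neuronal tubulin, and Slc17a6, the vesicular glutamate transporter of RGCs, went the other way at 3d, at 1.45 and 0.84. RGC subtype markers were at -0.46 at 3d and -0.59 at 7d (-0.32 and -0.39 outside the class), with Foxp2 at -2.03 and -1.72 and Spp1, an osteopontin gene of alpha RGCs, at 0.91 and 3.43. Presynaptic and excitability genes were at -0.25 at 3d and -0.30 at 7d, with the sodium channel gene Scn1a at -1.78 at 3d. Within cluster 28 alone the 7d medians of the identity and subtype lists were 0.14 and 0.15, and subtracting estimated free RNA put the identity median at 0.034, so their direction at 7d rests on these choices.

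Cholesterol synthesis genes in RGC-like nuclei were higher early and lower late, at 0.99 at 2h (0.83 to 1.05), 1.19 at 8h (1.09 to 1.30), -0.72 at 1d (-0.80 to -0.50), -0.83 at 3d (-1.04 to -0.60) and -0.99 at 7d (-1.25 to -0.83). All 12 members had an interval above 0 at 2h and at 8h, and 10 had one below 0 at 7d. In amacrine-like nuclei the same list was at 0.40, 0.44, 0.12, 0.31 and -0.19, and in all nuclei outside the class at 0.11, 0.33, -0.30, -0.08 and -0.47, with the sign of the RGC-like nuclei at each time. In astrocyte-like nuclei at 1d it was at -1.23 (-1.81 to -0.60). Horizontal-like nuclei had it at 0.56, 0.29 and 0.46 (0.16 to 1.04) at 2h, 8h and 1d, of the opposite sign to RGC-like nuclei at 1d.

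**Figure D2:**
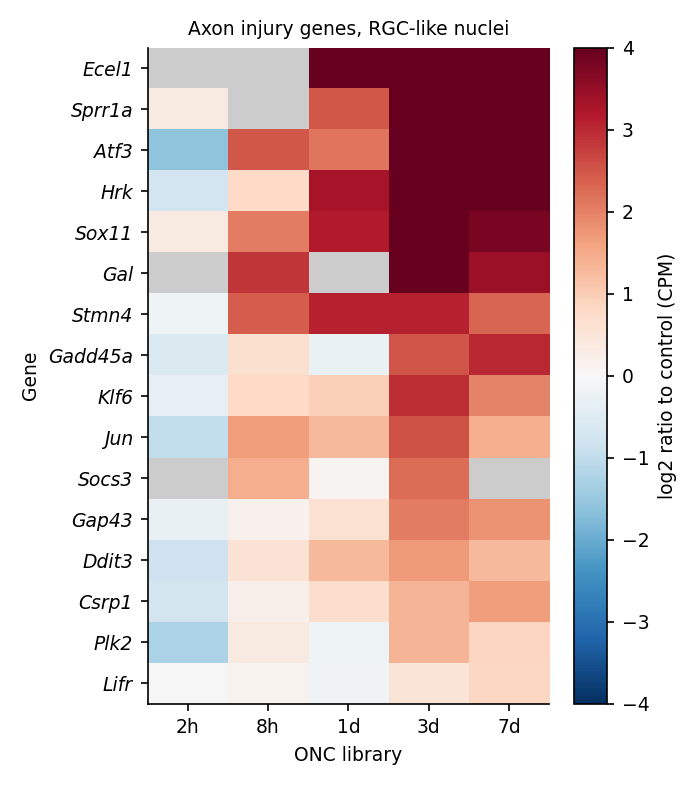
Log2 ratio to control (colour) of the 16 axon injury and regeneration genes in RGC-like nuclei in each ONC library; grey marks genes with fewer than 10 UMIs in the 2 libraries compared, and ratios past 4 take the end colour. Of the measured genes, 15 of 16 are at least 2-fold higher at 3d and 0 at 2h.

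By the rule for single genes, the RGC-like nuclei at 8h were led by Creb5, a CREB-family transcription factor (ENSMUSG00000053007, chromosome 6, 53287270 to 53700376), at 3.52 (3.05 to 4.06), and it stayed at 5.35, 4.73 and 5.05 at 1d, 3d and 7d. Mmp12, a matrix metalloproteinase gene (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), was at 3.60, 7.17, 8.49 and 7.06 at 8h, 1d, 3d and 7d, from 3 UMIs in control. In nuclei outside the class Mmp12 was at 1.43 (-0.18 to 3.63), 3.52, 5.67 and 3.46 at these times, so it was higher there too from 1d on. Dusp16, a MAP kinase phosphatase, and Serpina3n, an acute phase protease inhibitor, were at 2.47 (2.12 to 2.85) and 4.22 (2.17 to 10.14) at 8h, and Scel, a cornified envelope gene, at 4.67 at 1d. Dusp16, Serpina3n and Scel were at -0.10, 2.17 and 1.45 outside the class in the same libraries. Crct1 and Clca3b had no UMI in control and were at least 189-fold and 119-fold higher at 3d, taking 3 counts as the limit of a 0, and the lower limits of their binomial intervals were 7.26 and 6.58 on the log2 scale. Crct1 was at 6.24 and Clca3b at 1.27 outside the class at 3d. At 7d the axon guidance gene Sema3c was at 6.22 (4.99 to 8.29) and -1.43 outside the class, and Trim54 was at least 36.3-fold higher. At 2h Dsp, a desmosome gene, was at 4.51 (2.51 to 10.42) and Hao1 at least 6.25-fold higher, against log2 ratios of 1.09 and 2.64 outside the class. Lower genes were Prss22 at 2h, at -4.70, Lypd2 and Plekhs1 at 8h, at -5.05 and -3.16, the nicotinic receptor gene Chrna6 and Aifm3 at 3d, at -4.13 and -4.07, and Prlr and Lama4 at 7d, at -3.97 and -3.96. In the same order these lower genes were at -2.94, -2.41, -0.25, -1.32, -0.89, -1.29 and -0.93 outside the class. Tnf had 24 UMIs in control and 0 at 1d. In thinned RGC-like nuclei of 1000 UMIs, 0.114% of control and 12.6% of 3d nuclei had an Atf3 UMI, 1 and 15 nuclei being left out as shallower. The unthinned shares were 1.71% and 44.2%, at median depths of 6900 and 7863 UMIs. In cone-like nuclei, taken as background, the thinned shares were 0.400% and 1.71% and the unthinned ones 0.888% and 4.85%, with 14 and 7 nuclei left out and medians of 2112 and 2574 UMIs.

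Clusters 4 and 51 are given by number because the 10 leading genes of cluster 4 held Flt1, an endothelial marker, and none of the Müller glia markers, although all 10 of those markers were raised in it. Cluster 4 held every such nucleus in control and at 2h, and cluster 51 held 227 of 859 at 3d. Reactive gliosis genes, the glial injury programme, were at a list median of -0.02 at 2h, 1.25 at 8h (0.88 to 1.70), 0.87 at 1d (0.65 to 1.18), 2.49 at 3d (2.25 to 2.80) and 1.53 at 7d (1.23 to 1.75). At 3d 15 of 19 members were at least 2-fold higher. Gfap, the intermediate filament gene of reactive glia (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), was at -0.89, 0.71, 0.85, 3.43 (2.70 to 4.37) and 1.57, and Osmr, the oncostatin M receptor (ENSMUSG00000022146, chromosome 15, 6813577 to 6874969), at 0.92, 2.57, 1.70, 3.16 and 2.10. Outside the 2 clusters the list was at 0.37, 0.17, 1.75 and 1.10 from 8h to 7d. Against the 8h library its 1d and 7d medians were -0.52 and -0.23. The STAT3 and gp130 list was at -0.38 at 2h, 1.55 at 8h, 0.49 at 1d, 2.20 at 3d and 0.91 at 7d, with Socs3, the feedback inhibitor of this pathway, at 4.04 at 3d (2.65 to 6.56). Stat3 itself was at 1.67 at 8h against 0.83 outside the clusters, and at 2.20 at 3d against 2.46.

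Complement genes in clusters 4 and 51 were at -0.68 at 2h, 0.11 at 8h, 0.43 at 1d, 1.53 at 3d (1.01 to 2.10) and 0.92 at 7d, with 5 to 8 of 15 members measured, and outside the clusters at -0.14, 0.02, 0.48, 1.21 and 0.74. C4b, a complement component, was at 2.40, 1.64, 2.43 and 2.51 from 8h to 7d, and Serping1, the C1 inhibitor, at 2.03 at 8h. Interferon response genes were at 0.23, 0.05, 0.24, 1.11 (0.95 to 1.44) and 1.30 (1.09 to 1.53), and MHC class I genes at -0.03, 0.80, 0.01, 0.73 and 0.89. Immediate early genes were at -0.64 at 2h, 0.42 at 8h, -0.08 at 1d, 1.51 at 3d and 0.14 at 7d. At 2h complement genes were at 0.064 under naming by marker score, so their direction rests on the processing. Immediate early genes were at 0.59 at 2h after subtraction of free RNA. That step took 85.1% of the library profile in control and 64.3% at 2h. How far this unequal share alone moved the median was not tested, so the value does not decide the direction. The oxidative stress and NRF2 list was at 0.40, 0.58, -0.02, 0.60 and 0.04, with the metallothionein gene Mt1 at 2.10 at 3d. The Müller glia homeostasis list was at -0.19, 0.11, -0.15, -0.55 (-0.66 to -0.41) and -0.30 (-0.39 to -0.20), and outside the clusters at -0.49, -0.60, -0.52, -0.52 and -0.19. Within it Glul, the glutamine synthetase gene, was at -1.03 at 3d, and Sox9, a glial transcription factor, at 1.55. Neurogenic and progenitor genes were at -0.21, 0.30, -0.37, -0.08 and -0.35, each with an interval that includes 0 except at 8h (0.04 to 0.63).

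By the rule for single genes, Cdh13, an adhesion gene (ENSMUSG00000031841, chromosome 8, 118283733 to 119324921), was at 4.36 at 3d (4.16 to 4.58) and 2.69 at 7d in clusters 4 and 51, and at 0.26 and -0.20 outside them. Adamtsl3, a matrix protein gene, was at 3.90, 5.29 and 3.68 at 8h, 3d and 7d. Fosl1, an AP-1 transcription factor, was at 6.45 at 3d (4.53 to 12.34) from 1 UMI in control, and the noncoding RNA Pvt1 at 5.81 (4.25 to 9.18) from 2 UMIs. The iron carrier Trf and the growth factor Hgf were at 2.09 and 2.53 at 8h, and the MHC gene H2-Q4 and Trim30d at 4.29 and 3.66 at 7d. At 2h the arrestin-domain gene Arrdc2 was at 3.57 (2.92 to 4.38), and the glucocorticoid response list at 0.72 (0.46 to 0.94), with Fkbp5, a feedback regulator of the glucocorticoid receptor, at 1.93. That list was at 0.05, -0.26, -0.03 and 0.18 at later times, so only its 2h median was apart from 0 by 1.5-fold or more. Fstl4 was at 2.96 and 2.36 at 2h and 1d, Dchs2 at 2.72 and Slc24a2 at 2.09 at 1d. Lower genes included the lens genes Mip, at -5.54, -4.69 and -5.90 at 2h, 3d and 7d and with 47 UMIs in control and 0 at 8h, and Cryaa, at -5.51, -4.46 and -4.28 at 8h, 1d and 7d, as well as Nefh, a neurofilament gene of RGCs, at -3.25 at 3d. Outside the clusters Nefh was at -2.67, Cryaa at -3.25, -2.53 and -0.97, and Mip at -0.53, 0.07 and -0.65. In nuclei thinned to 1000 UMIs a Gfap UMI was seen in 0.462% of control and 6.09% of 3d nuclei, with 4 and 5 left out, and unthinned in 1.15% and 14.8% at median depths of 2429 and 3304 UMIs. Cone-like nuclei, the background, gave 0.601% and 1.96% thinned and 1.18% and 4.61% unthinned.

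**Figure D3:**
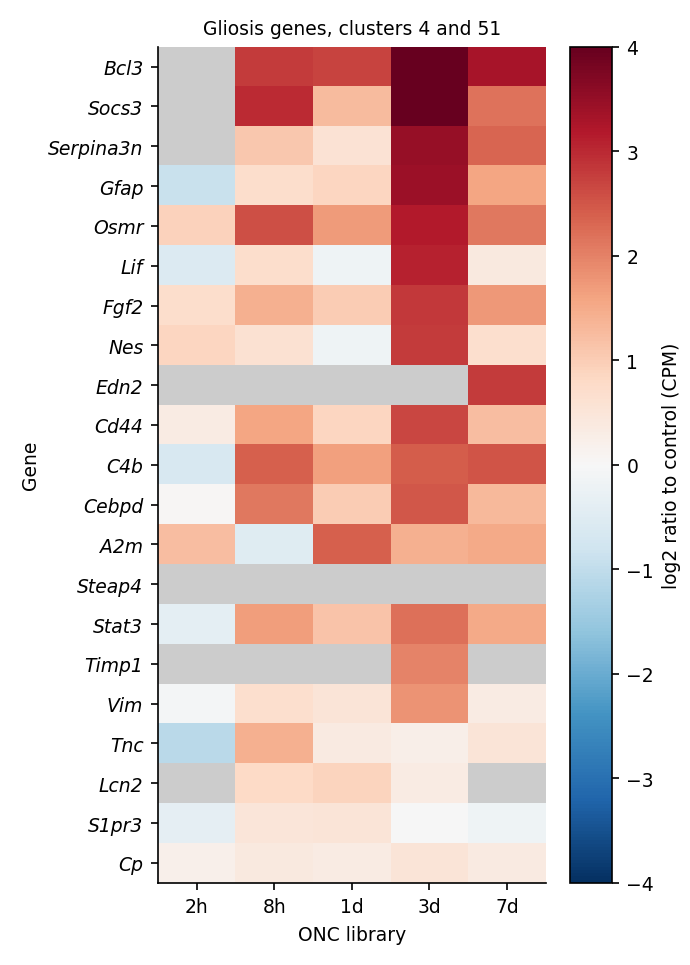
Log2 ratio to control (colour) of reactive gliosis genes in clusters 4 and 51 in each ONC library; grey marks genes with fewer than 10 UMIs in the 2 libraries compared, and ratios past 4 take the end colour. Of 19 measured genes, 15 are at least 2-fold higher at 3d.

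**Figure D4:**
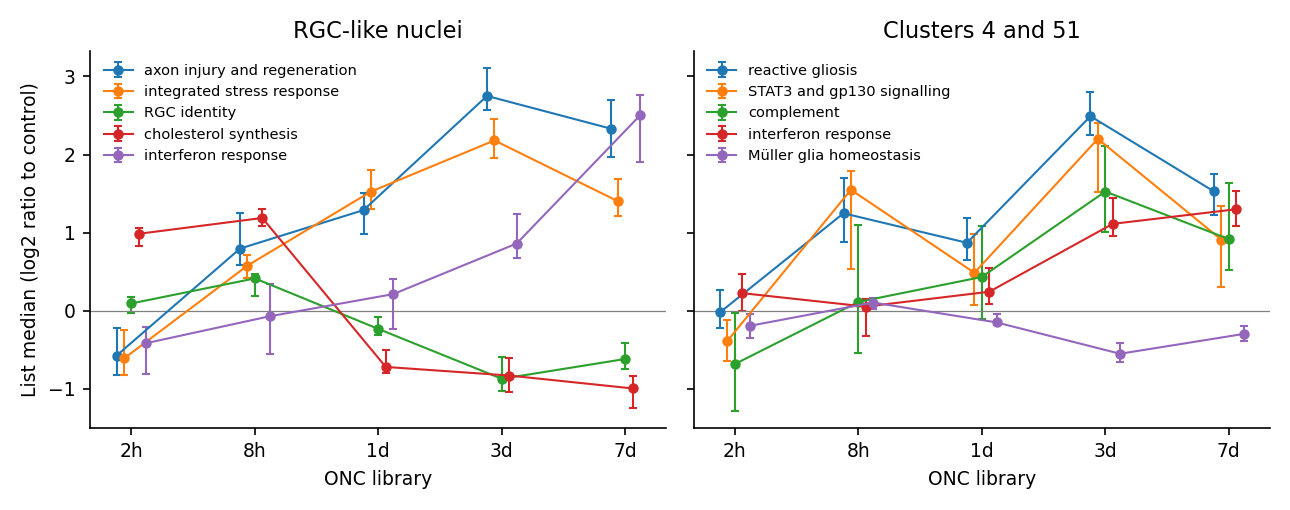
Median log2 ratio to control of 5 gene lists in RGC-like nuclei (left) and in clusters 4 and 51 (right) per ONC library; bars are 95% intervals for counting error. The axon injury median in RGC-like nuclei is 2.75 at 3d, the interferon median there is 2.50 at 7d, and the gliosis median in the clusters is 2.49 at 3d.

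Each list median has a percentile among 10000 random lists of the same size matched on expression, as a description of these libraries. The axon injury list in RGC-like nuclei stood at the 0.130 percentile at 2h and at 100 at the other times, and the gliosis list in clusters 4 and 51 at 59.99 at 2h and 100 afterwards. Cholesterol synthesis in RGC-like nuclei stood at 100 at 2h and 8h and at 0 at 1d, 3d and 7d. Of 34 lists in RGC-like nuclei, 1, 4, 2, 9 and 10 medians were at least 1.5-fold higher with an interval clear of 0 at 2h, 8h, 1d, 3d and 7d, and 7, 2, 7, 4 and 6 were as far lower. In clusters 4 and 51 there were 1, 3, 1, 10 and 5 higher and 8, 2, 8, 4 and 5 lower.

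The list of gliosis genes was also higher at 3d in 4 other classes, with medians of 1.89 in rod-like (1.51 to 2.16), 1.43 in cone-like (1.07 to 1.89), 1.67 in bipolar-like (1.27 to 2.02) and 1.74 in amacrine-like nuclei (1.33 to 2.00). At 7d these were 1.37, 0.82, 1.14 and 0.88. In horizontal-like nuclei 6 of 22 members were measured at 3d, with a median of 1.39 (0.40 to 2.23) that was -0.074 after thinning, and the 7d interval included 0. The STAT3 and gp130 list at 3d was at 0.99, 1.01, 0.99 and 1.02 in the 4 classes, and in rod-like nuclei it was at 0.72 at 8h (0.27 to 0.90). Stat3 in rod-like nuclei was at 3.12 at 3d (2.95 to 3.29), and Edn2, an endothelin known from stressed photoreceptors, at 2.54 and 2.88 at 3d and 7d, against 3.87 and 4.19 outside the class. Cluster 1 held most rods in control and at 8h (74.0% and 84.5%), and cluster 0 held the largest part in the other libraries. With estimated free RNA subtracted, the gliosis median of cone-like nuclei at 7d was -1.11, but that estimate takes 99.8% of the library profile in control and 87.4% at 7d, which leaves little to measure. In cone-like nuclei Kif4, a kinesin gene, was at 3.71 at 2h (3.39 to 4.06) and Pdzd11 at 2.61, and Sh2d2a and Vwa3a were at least 9.67-fold and 7.17-fold higher there. Outside the class these genes were at 1.85, 0.18, 2.11 and 1.20 in the same order. Bipolar-like nuclei had the guidance gene Slit3 at 3.99, the protease inhibitor A2m at 3.75, Zbtb7c at 3.05 and Scube1 at 4.38 at 3d, Ifi27l2a at least 7.27-fold higher and Gpnmb at -3.61 at 7d. In the same order these genes were at 0.95, 2.02, 0.54, 1.82, 1.36 and -0.91 outside the class. Rod-like nuclei had Scube1 at 4.44 at 3d, Ucn at least 10.9-fold higher at 7d, Cxcl2, a chemokine, at least 9.78-fold higher at 8h, and Ctla2a and Trarg1 at -3.82 and -3.89 at 1d and 7d, against -2.38 and -3.24 outside the class. In nuclei other than rods Scube1, Ucn and Cxcl2 were at 1.63, 4.76 and 3.83 in the same libraries, so they were higher there too. Ecel1, which led in RGC-like nuclei at 3d and 7d, was also at least 17.7-fold higher in rod-like and at least 7.12-fold higher in cone-like nuclei at 7d. Its levels there were 8.46 and 8.99 CPM, against 159.6 CPM in RGC-like nuclei at 7d. Sprr1a, a member of the axon injury list, was at least 17.9-fold higher in rod-like nuclei at 3d, at 8.58 CPM. Free RNA was not subtracted in rods and took most of the profile in cones. Expression of these genes by photoreceptors was therefore not shown.

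In horizontal-like nuclei (117 in control and 90 to 165 in the ONC libraries) Usp29, Pde10a, a phosphodiesterase gene, and Adamts18 were at 2.47, 2.13 and 2.50 at 2h. Outside the class they were at -0.07, -0.25 and 0.31. Pde10a was at -0.15 at 2h when each nucleus took the class with its highest marker score. Of the photoreceptor genes, Rbp3 and Rtbdn were at -2.65 and -2.74 at 1d and Pdc at -2.09 at 2h in horizontal-like nuclei. Outside the class these 3 genes were at -1.75, -0.75 and -1.33, so they were lower there too. In amacrine-like nuclei Crygb, a lens gene, was at 2.67 at 3d and at 2.69 outside the class, Alpk3 at 3.41 at 2h and Crh at -4.41 at 2h, and the lens gene Cryaa was at -3.32, -3.65 and -3.68 in amacrine-, cone- and bipolar-like nuclei at 8h, and outside each class at -3.35, -3.33 and -3.31. Alpk3 and Crh were at 2.22 and -0.99 at 2h outside the amacrine-like nuclei. Ly6a was at -3.63 in cone-like nuclei at 8h and at -2.20 outside the class. Rod phototransduction genes, which amacrine cells do not use, had medians in amacrine-like nuclei of -0.96, 0.33, -1.26, -0.70 and -0.57. Heat shock and tissue handling genes were at -0.75, 0.15, -0.83, -0.27 and -0.46 in the same nuclei. Ribosomal protein genes took 1.87%, 0.871%, 1.92%, 0.819%, 1.23% and 1.14% of all UMIs from control to 7d. The rod list in amacrine-like nuclei and ribosomal protein genes were thus lower in the 2h and 1d libraries than in the control and 8h libraries.

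A small set of genes set the 2h and 1d libraries apart in every main class. Pttg1, securin (ENSMUSG00000020415, chromosome 11, 43420250 to 43426251), was 104-fold lower over all nuclei of these 2 libraries than over the other 4. Rbp7, a retinoid-binding protein (ENSMUSG00000028996, chromosome 4, 149449687 to 149454978), was 145-fold higher, and its neighbour Nmnat1, an NAD synthesis enzyme (ENSMUSG00000028992, chromosome 4, 149467572 to 149485202), 7.13-fold higher. Tpm3-rs7 was 14.96-fold higher and Rbm46os 8.79-fold. In RGC-like nuclei Nmnat1 was at 3.302 at 2h, Rbp7 was at 6.52 and 7.44 at 2h and 1d and Pttg1 at -5.07 and -5.38, and outside the class Rbp7 was at 6.55 and 6.90.

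Astrocyte-like nuclei numbered 104 in control and 47, 24, 52, 39 and 47 afterwards, so only the 1d library reached the 50 nuclei set for a comparison. There reactive gliosis genes were at 0.95 (0.59 to 1.17), with Gfap at 1.27 (0.83 to 1.74) and 0.13 outside the class. Microglia-like, endothelial-like and pericyte-like nuclei fell short of 50 in control or in every ONC library compared, so their genes are not compared.

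Among ligands and receptors fixed beforehand, 22 of 39 ligands and 25 of 42 receptors were detected in RGC-like nuclei, and 19 and 33 in clusters 4 and 51. In RGC-like nuclei Csf1, the colony stimulating factor that acts on microglia, was at 2.69 at 3d (1.90 to 3.63), Gas6, a ligand of TAM receptors, at 1.96, the fibroblast growth factor receptor Fgfr1 at 3.06 (2.71 to 3.44), the hyaluronan receptor Cd44 at 3.47, and the GDNF coreceptor Ret at 2.34 at 7d. Tek, an angiopoietin receptor, was at 1.43 at 1d and 1.63 at 3d, against -0.11 and -0.47 outside the class. Bdnf, a neurotrophin, was at -1.39 at 2h in RGC-like nuclei and at 2.87 at 3d in clusters 4 and 51. Those clusters also had Lif, an interleukin-6 family cytokine, at 3.08 (3.67 outside the clusters), Fgf2 at 2.83 and the endothelin receptor Ednrb at 2.43 at 3d, while the chemokine gene Cx3cl1 was at -2.07 and -2.01 at 3d and 7d. The tumour necrosis factor receptor Tnfrsf1a was at 2.48 there at 8h and 2.35 at 3d. Levels of a ligand in one class and of its receptor in another were not combined into a score.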

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

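The tests of a crush response and of free RNA for Pttg1, Rbp7 and Nmnat1, of a shift of the whole library, of a shift in most nuclei, of cluster 28 at 1d and of cluster 15 at 3d and 7d for the cholesterol genes, and of pericyte depth, misplaced nuclei and the control preparation for vascular nuclei were chosen only after those results were seen.

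Several of the gene lists printed here had medians of opposite sign in 2 of the ONC libraries, each by at least 1.5-fold and with an interval clear of 0; in each case the difference was not tested, since each time has 1 library. In RGC-like nuclei integrated stress response genes were at 2.18 at 3d and -0.61 at 2h, MHC class I genes at 1.35 at 7d and -0.86 at 2h, cholesterol synthesis genes at 1.19 at 8h and -0.99 at 7d, immediate early genes at 1.24 at 3d and -1.01 at 2h, and crystallins at 1.13 at 3d and -2.15 at 8h. The crystallin list was at 1.34 and -2.86 outside the class, so it differed between these libraries in other nuclei too. In clusters 4 and 51 complement genes were at 1.53 at 3d and -0.68 at 2h, and immediate early genes at 1.51 at 3d and -0.64 at 2h. The stress, MHC class I and immediate early lists were at -0.51, -0.36 and -0.91 at 2h outside the RGC-like nuclei, and the complement and immediate early lists at -0.14 and -0.97 outside the clusters, so the stress and immediate early lists were about as low in other nuclei. In the 2h library rod RNA in other classes and ribosomal protein genes were also lower than in control.

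Cholesterol synthesis genes in RGC-like nuclei were higher at 2h and 8h and lower from 1d on. An equal shift of the whole library or free RNA would put the amacrine-like nuclei near the same medians. However, the smaller of the 2 gaps between the classes, at 8h and 7d, was 0.75 on the log2 scale. A shift in most nuclei from 1d on cannot be told apart from a change in RGC-like nuclei by the test used. The list was lower outside the class too, and the smallest gap, at 1d, was 0.42, between the bounds set for the test. At 3d and 7d the list was at -0.08 and -0.47 outside the class, against -0.83 and -0.99 in it. These times were not tested apart from 1d. Other RGC subtypes in the early libraries would leave cluster 15 near 0, but its smaller early median was 0.69 (0.58 to 0.99). A different mix from 1d on would leave cluster 28 near 0, but it was at -0.99 at 1d (-1.25 to -0.64). Its larger median at 3d and 7d was -1.17 (-1.73 to -0.88). These medians speak only for the nuclei of each cluster, and neither cluster was shown to be a single subtype. Cluster 15 was below 0 as well at 1d, at -0.56 (-0.87 to -0.28), and at 7d, at -0.69 (-1.73 to -0.29) from 14 nuclei, but there a different mix late cannot be told apart from lower levels, since its larger late median, from 21 nuclei at 3d, was -0.25 with an interval that includes 0 (-0.79 to 0.11). Cluster 28 held 59 of 488 RGC-like nuclei at 1d, 72 of 539 at 3d and 56 of 217 at 7d. Cluster 25 held 435 at 3d and 115 at 7d, but only 15 in control, and its median was not tested. For the class as a whole a different mix from 1d on therefore stays open. A response of the RGCs to the crush and differences between mice or preparations also stay open and untested.

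Endothelial-like and pericyte-like nuclei were fewer in each ONC library than in control. More shallow barcodes in control are argued against by nuclei with at least 2000 UMIs, where the highest endothelial ratio was 0.291 (upper bound 0.443), but for endothelial-like nuclei alone. For pericyte-like nuclei shallow barcodes cannot be told apart from fewer nuclei, since 7 control nuclei are that deep and the highest ratio was 0.885 (0.246 to 3.07). Vascular nuclei placed in other clusters or removed as doublets cannot be told apart from fewer nuclei, since endothelial marker counts over all barcodes were at most 0.640 times control, between the bounds set for the test. More vessel tissue in the preparation cannot be told apart either, with 1 control library, and no biological explanation was tested.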

How the results depend on the processing

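The share of nuclei in named clusters, the 2h and 8h libraries as reference, cluster 28 alone and cluster 4 alone were chosen after seeing the data; the other alternatives were planned. Each changed 1 choice, apart from the filter on nuclei, which changed the limits on genes and on mitochondrial UMIs together, and thinning, which also left out shallower nuclei. No paired analysis was possible because each group is 1 library and no label links retinas across groups. Free RNA was not subtracted in rods, whose genes set its estimate, and alternatives for gene levels in microglia-, endothelial- and pericyte-like nuclei were not run, since those levels are not compared. The cause was not tested for any of the differences below unless the sentence states it. Of 360 values of class shares 234 lay within the counting interval of the reported value, 120 lay outside it and 6 were counted as changes of direction. Of 2323 list medians the numbers were 1747, 544 and 32, and of 817 values of single genes 675, 137 and 5. Changes of direction were counted only for results called different from control: 25 of 60 shares, 77 of 177 list medians and all 105 single genes. Changes of sign in the other results are not in these counts. The ratio of the RGC share at 2h went from 0.958 to 1.08 among nuclei other than rods and was counted as outside the interval. A filter of 500 genes and 5% mitochondrial UMIs put the ratio of the RGC share at 0.8001, 0.802, 0.802, 0.744 and 0.271 from 2h to 7d. Naming by marker score put it at 0.760, 0.821, 0.711, 0.440 and 0.195, the axon injury median at 7d at 1.56, the gliosis median of clusters 4 and 51 at 1d at 0.56 and their complement median at 2h at 0.064; it turned the ratios of the horizontal share at 2h and 1d to 0.862 and 0.863, those of the astrocyte share at 2h, 3d and 7d to 1.01, 1.36 and 1.20, and in horizontal-like nuclei at 2h Pde10a to -0.15 and the gliosis median to -0.32. That median was -0.71 with members of at least 1 UMI. Per 100 amacrine-like nuclei the RGC ratio was 0.780, 0.815 and 0.802 at 2h, 8h and 1d. Among nuclei other than rods it was 1.08, 1.06 and 0.749 at 2h, 1d and 3d, and in named clusters 0.777, 0.776 and 0.981. At resolution 2 the ratio of the rod share at 3d was 1.38 and the axon injury median at 1d 1.68. Without doublet removal that median was 1.56 and the gliosis median at 8h 0.72.

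With estimated free RNA subtracted, axon injury genes in RGC-like nuclei were at -0.17, 1.74, 2.61, 3.78 and 3.36 from 2h to 7d. Gliosis genes in clusters 4 and 51 were then at 1.80, 1.45, 3.07 and 2.05 from 8h. The share subtracted in these clusters was 85.1% in control and 84.6%, 59.8%, 65.7% and 61.2% from 8h to 7d. How far this unequal share alone raised the medians was not tested, so they do not show stronger gliosis. After subtraction the RGC identity median at 7d was 0.034 and the immediate early median of clusters 4 and 51 at 2h 0.59. The cone gliosis median at 7d was -1.11, where nearly the whole profile is subtracted. In amacrine-like nuclei the rod list was then at 0.44, 0.46 and 0.68 at 2h, 1d and 3d, and heat shock genes at 0.31 and 0.74 at 2h and 1d; the subtraction removes the rod genes it is set from, so the rod list is turned by construction. Thinned to 1000 UMIs, axon injury genes were at 0.027, 1.52 and 2.18 at 2h, 8h and 1d, and gliosis genes in horizontal-like nuclei at -0.074 at 3d. In cluster 28 alone they were at 0.56, 1.53 and 2.56 at 8h, 1d and 3d, the identity and subtype medians at 7d at 0.14 and 0.15 and the MHC class I median at 2h at 0.50. In cluster 4 alone the gliosis median at 3d was 2.09.

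The median of the other 4 ONC libraries as reference holds the 3d and 7d libraries, and so lowers early values by construction. It put axon injury genes at -2.58, -0.83, -0.58, 1.73 and 1.13 from 2h to 7d and gliosis genes in clusters 4 and 51 at -1.49, 0.31, -0.50, 1.35 and 0.0504. It also turned the STAT3 list at 8h in RGC-like and rod-like nuclei to -0.20 and -0.064, the rod list in amacrine-like nuclei at 3d to 0.064, crystallins in RGC-like nuclei at 7d to 0.071, gliosis genes in horizontal-like nuclei at 2h to -0.25 and astrocyte gliosis at 1d to -0.98. Of single genes it turned Creb5, Mmp12 and Dusp16 in RGC-like nuclei at 8h to -1.38, -3.52 and -0.10, and Mip in clusters 4 and 51 at 3d to 0.90. Against the 2h library axon injury genes were at 1.60, 2.12 and 3.398 at 8h, 1d and 3d, gliosis genes in clusters 4 and 51 at 1.18 at 7d and the rod list in amacrine-like nuclei at 0.32 at 3d. Against the 8h library axon injury genes were at -1.60, 0.31, 1.52 and 1.33 at 2h, 1d, 3d and 7d, and gliosis genes in clusters 4 and 51 at -1.25, -0.52, 1.09 and -0.23; cholesterol genes in RGC-like nuclei at 2h were at -0.37, crystallins there at 0.19 and 1.46 at 1d and 7d, the STAT3 list of clusters 4 and 51 at 7d at -0.14 and astrocyte gliosis at 1d at -1.30.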

Other observations

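The tests of a crush response and of free RNA given here were chosen only after the result was seen, and the count over pairs of libraries before.

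Over all nuclei, 16 genes were at least 4-fold apart between both of the 2h and 1d libraries and every other library, and 15 of them went the same way in all 7 main classes. On chromosome 4, Rbp7 lies near Nmnat1, and Tmem274 (149477378 to 149483549), 5.20-fold higher, lies within the span of Nmnat1. On chromosome 3, Rbm46os (82876705 to 82943638) and Gm30097 (82926665 to 83008488) overlap and were 8.79-fold and 13.3-fold higher. Gm15758 on chromosome 8 and Gm17167 on chromosome 4 were 297-fold and 102-fold lower. Gene models and retrotransposed copies can share reads with close relatives, so levels of the gene models and of Tpm3-rs7 are uncertain.

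For Pttg1, Rbp7 and Nmnat1, the smallest of their 3 differences was 2.83 where ribosomal protein genes differed by 0.857. These genes were picked for their large differences between the libraries, so this comparison cannot decide on free or cytoplasmic RNA. Mice of another genetic background in these 2 libraries may be a source of the pattern, although the labels name C57BL/6J for all. A response to the crush at 2h and 1d alone cannot be told apart from a difference between libraries, with 1 library at each time. The count of 16 genes cannot tell the genetic background apart from other differences between the libraries, with 1 library at each time. Among the 15 pairs the next count was 15, for 3d and 7d, whose genes include injury genes such as Ecel1 and Edn2. That pair is therefore not free of a possible crush response, and the count after it was 5, for 8h and 1d. Comparisons of the 2h and 1d libraries with control could hold a difference in background too. The bound for a reading as genetic background was set at 1.5 times the next pair after the counts were seen. The prediction written before asked only for the highest count, which 16 meets.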
